A study of Drosophila melanogaster with 91 samples.

How the data were processed

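The samples were 91 single embryos of the fruit fly Drosophila melanogaster. Embryos were dechorionated, glued to a cover slip and watched under a microscope. Each was frozen at a set time relative to cellularization, the step at which membranes enclose the nuclei of the early embryo. The labelled times ran from -15 to 1335 min in steps of 15 min, with 1 embryo at each time. RNA from each embryo was amplified and sequenced by CEL-Seq, a multiplexed method in which barcoded reads come from the 3' ends of polyadenylated transcripts.

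The authors deposited 1 table of read counts per gene and embryo, not normalized. Per the submitters' processing notes, the tools were CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3 with genome build BDGP5; the order of use, the strand setting of the counting and any treatment of molecular identifiers are not given in the sources used here. A deposited sample sheet of the other kind, whose values are not measurements, gives the sequencing lane and the library index of each embryo. By that sheet the embryos formed 4 library pools that followed labelled time: pool 4 (-15 to 315 min, 23 embryos) and pool 5 (330 to 645 min, 22 embryos) on lane 3, and pool 6 (660 to 990 min, 23 embryos) and pool 7 (1005 to 1335 min, 23 embryos) on lane 4.

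The count table held 15682 fly gene identifiers, 92 ERCC spike-in transcripts (synthetic RNAs added in known amounts) and 5 summary lines. Of all counts, 60.7% fell on fly genes, 3.29% on spike-ins, 16.6% outside annotated genes, 2.44% on places that more than one gene could claim, and 17.1% were not aligned. Library sizes and tests used the fly genes alone. Of the gene identifiers, 15002 matched a symbol in the gene name table given with the reference annotation; the other 680 carried 9.06% of gene counts and are named by identifier. The reference was another build than that of the counts, so no coordinates are given. Reads of near-identical gene copies, such as Hsp70Aa and Hsp70Ab or the paired ribosomal protein genes, could be split between copies by the counting, and values of such genes are uncertain for the single copy.

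The median library held 1644070 gene counts, with a range from 3662 to 3308020. In 6 libraries the total lay under 548023 gene counts, the median divided by 3: those at 120, 210, 825, 1065, 1155 and 1170 min. No pair of libraries had identical counts, and the highest Pearson correlation between any pair was 0.982. Levels are given as counts per 1000000 gene counts (CPM), as mean ± SD over embryos.

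No time point had more than 1 embryo. Embryos were therefore grouped into 7 consecutive windows of 13 embryos by labelled time: -15 to 165, 180 to 360, 375 to 555, 570 to 750, 765 to 945, 960 to 1140 and 1155 to 1335 min. The spread within a window holds both differences between embryos and change over the 195 min it spans. The labels do not say which mothers or plates the embryos came from, so p-values measure the spread between these embryos; nothing pairs embryos across windows. Each of the 6 pairs of adjacent windows was compared with edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment, using only the 26 embryos of both windows. A linear trend in labelled time was fitted within window 1, per 60 min. Variation over all 91 embryos was tested with a natural cubic spline of labelled time with 5 degrees of freedom. Genes with an adjusted p under 0.05 were called. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F statistic.

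For each embryo the most similar other embryo was the one with the highest Spearman correlation of log2(CPM + 1) over 8717 genes. Correlations of both times were tested with 100000 permutations, two-sided. A second estimate of age compared each embryo with a spline of the other 90 embryos over the 1000 most variable genes.

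There were 23 gene lists: maternal egg and germ plasm, cellularization, gap and pair-rule segmentation, segment polarity, dorsoventral patterning and gastrulation, Hox, neuroblast and neurogenesis, neuronal differentiation, glia, muscle, cuticle and chitin, ecdysone, cell cycle and DNA replication, trachea, gut and Malpighian tubule, hemocyte and fat body, glycolysis and lactate, ribosomal proteins, oxidative phosphorylation, heat shock, eggshell and yolk of maternal tissue, sex determination and dosage compensation, and sensory and chemosensory late genes. Of their genes, 501 were in the table and none stood in more than one list. Lists were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation. Genes named in the text are, in each comparison, the 8 with the largest rise and the 8 with the largest fall among called genes with at least 50 CPM in the higher window and a symbol other than a CG or CR number. For the spline the rule takes the 10 with the smallest p. Up to 4 called members of each list, other members with their values, and the 5 most abundant genes of a window were also open to naming. The windows, tests, gene lists, naming rule and the first set of alternative settings were fixed before the data were examined.

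The tests were checked on simulated counts drawn from the real means and library sizes with 200 changed genes. Genes changed by a log2 of 2 were recovered in 63% of cases from window 1 to window 2, 70% from window 3 to window 4 and 58% from window 6 to window 7; for a log2 of 1 the shares were 18%, 23% and 13%. In the trend test 16% of genes changing by a log2 of 1 per 60 min were recovered. In the spline test 46% of genes with a rise of 2 on the log2 scale and 6% of those with a rise of 1 were recovered.

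The alternative settings of that first set were DESeq2 size factors in the same edgeR test, no filter or a stricter filter of 10 CPM in 13 embryos (7 in the trend) on low counts, leaving out the 6 shallow libraries, thinning every other library to 561108 counts, library pool as a covariate, DESeq2 1.42.0, limma voom, a fit of all 91 embryos, splines with 3 or 8 degrees of freedom, and the first 6 against the last 6 embryos of window 1. Alternatives added after the data had been seen were scaling by spike-in counts, fits within a single library pool, leaving out the embryo at 120 min, leaving out each embryo in turn, and leaving out libraries in which spike-ins took more than 6%, 8% or 10% of gene and spike-in counts. Other computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.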

Results

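Transcript levels were measured by CEL-Seq in 91 single Drosophila melanogaster embryos, 1 for every 15 min of labelled time from -15 to 1335 min relative to cellularization. The embryos were compared as 7 windows of 13 embryos each, windows 1 to 7 in order of labelled time. The median embryo gave 1644070 gene counts and the range ran from 3662 counts at 120 min to 3308020. Spike-ins took 96.0% of gene and spike-in counts in the library at 120 min, against window medians from 4.35% to 5.48%. The most abundant transcript in every window was mt:lrRNA (FBgn0013686), the large ribosomal RNA of mitochondria, with means from 76718 ± 22421 CPM (SD, n = 13) in window 5 to 106513 ± 42101 CPM in window 2. RpL21 (FBgn0032987), a protein of the large ribosomal subunit, ranged from 21542 ± 3333 CPM in window 5 to 38401 ± 4309 CPM in window 3. Act57B (FBgn0000044), an actin of muscle, entered the 5 most abundant transcripts in window 7 with 10695 ± 7639 CPM. The transcript FBgn0085364, which has no symbol in the name table used here, held 18310 ± 5470 CPM in window 1 and 9575 ± 4119 CPM in window 6.

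More genes were detected in the later embryos. Libraries of lane 3 (-15 to 645 min) had 6730 ± 1370 genes with at least 1 count (n = 45) and those of lane 4 (660 to 1335 min) had 8710 ± 1230 (n = 46). When libraries were thinned to 300000 gene counts the numbers were 6210 ± 758 (n = 44) and 7390 ± 826 (n = 46), a difference with a two-sided permutation p of 1e-05, the smallest the permutations can give. The permutations treat embryos as independent, but lane follows library pool and labelled time, so this p-value may be far too small. By pool the thinned numbers were 6280 ± 704 in pool 4 (n = 22) and 6130 ± 818 in pool 5 (n = 22), both on lane 3, and 7680 ± 700 in pool 6 (n = 23) and 7110 ± 859 in pool 7 (n = 23), both on lane 4, so that in neither lane was the mean higher in the later pool.

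**Figure D1:**
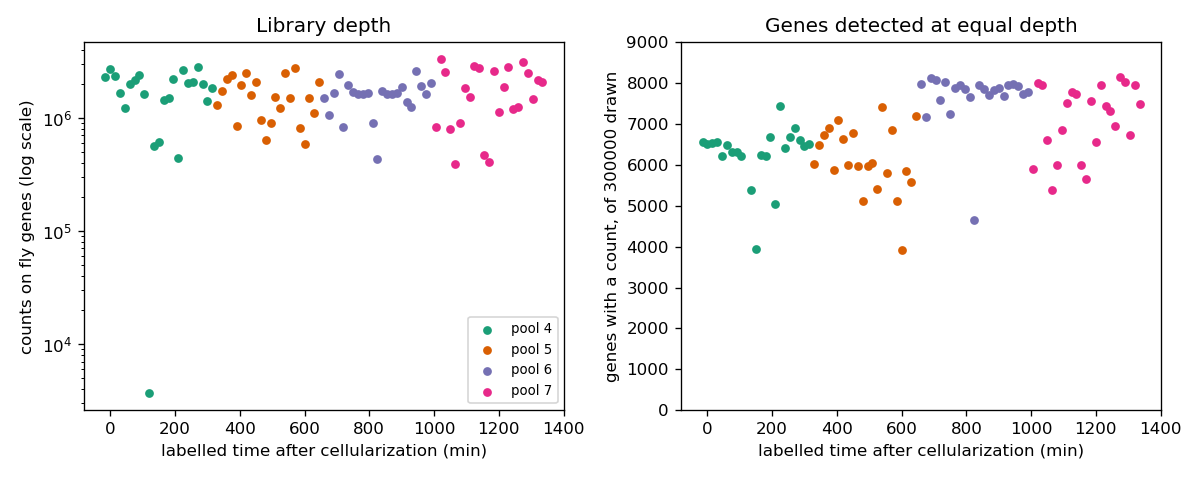
Gene counts per embryo on a log axis (left) and genes detected after thinning to 300000 gene counts (right) against labelled time in minutes, 1 point per embryo, coloured by library pool. The library at 120 min stands apart with 3662 gene counts, and pools 6 and 7 lie mostly above pools 4 and 5 in genes detected.

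The first question was which genes changed level over the whole course. Of 8717 genes tested, 7155 (82.1%) varied with labelled time by the edgeR F-test of the spline. Of these, 2346 (32.8%) had their highest mean in window 1 and 1538 (21.5%) in window 7. The genes named by the rule included genes of cuticle and muscle. The smallest adjusted p, 5.37e-28, was that of CG15597 (FBgn0037420), a gene outside the rule that was chosen after its values were seen. TwdlN (FBgn0039441), a cuticle protein of the Tweedle family, reached 4596 ± 4349 CPM in window 7 with an adjusted p of 1.26e-26. The cuticle gene Cpr65Ax2 reached 1325 CPM and Edg91, another cuticle gene, 218 CPM in that window. Vajk2 and Vajk3 reached 1295 and 1421 CPM. Mhc (FBgn0264695), the myosin heavy chain of muscle, had window means of 0.545, 1.36, 18.1, 432, 1395, 1137 and 1687 CPM, and Mp20, a muscle protein, reached 1909 CPM. Jon25Biii, a serine protease, averaged 869 ± 1826 CPM in window 7, an SD larger than the mean. Xrp1, a transcription factor gene, had its highest mean of 482 CPM in window 7, and bru3, an RNA-binding protein gene, its highest of 279 CPM in window 5.

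Early lists had their highest means in windows 1 and 2. All 16 tested genes of the maternal list varied and 15 of them were highest in window 1, as were all 6 of the cellularization list. The 23 tested genes of the cell cycle list all varied, 17 with the highest mean in window 1 and 6 in window 2. Gap and pair-rule genes varied in 15 of 15 cases, 9 highest in window 1 and 5 in window 2. Dorsoventral and gastrulation genes varied in 11 of 14 cases, 5 of these highest in window 2. Window 2 also held the highest means of 5 of 8 segment polarity genes, 4 of 8 Hox genes, 13 of 17 neuroblast genes and 3 of 5 trachea genes, all of which varied. The sex determination list varied in 5 of 8 genes, 3 of these highest in window 2.

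Lists of differentiated tissue had their highest means later. Of the 25 muscle genes, all of which varied, 15 were highest in window 7, as were 16 of 21 neuronal, 11 of 12 glycolysis and 7 of 13 gut genes, again all varying. The 32 cuticle genes all varied, with 14 highest in window 5, 9 in window 6 and 8 in window 7. Ecdysone pathway genes varied in 17 of 20 cases, 7 of these highest in window 5, and the 12 hemocyte and fat body genes all varied, 5 highest in window 5. All 7 glia genes varied and 3 were highest in window 4. Heat shock genes varied in 11 of 11 cases, with 9 highest in window 6, where 6 of 13 libraries held over 6% spike-ins, and 2 in window 1. Ribosomal protein genes varied in 80 of 82 cases by small amounts, a median fitted range of 1.91 on the log2 scale, and 45 were highest in window 7. The 58 oxidative phosphorylation genes all varied, 17 highest in window 1, 16 in window 5 and 20 in window 7. The 5 sensory genes and the 1 tested gene of the eggshell and yolk list varied too. Adjusted over the list alone, the number of varying genes was the same in each of the 23 lists. Within single library pools, with a spline of 3 degrees of freedom, 3412 genes varied in pool 4, 5 in pool 6 and 2 in pool 7. In pool 5 edgeR called 0 genes, with 549 at an unadjusted p under 0.05, and with pool as a covariate over all embryos it called 3146.

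**Figure D2:**
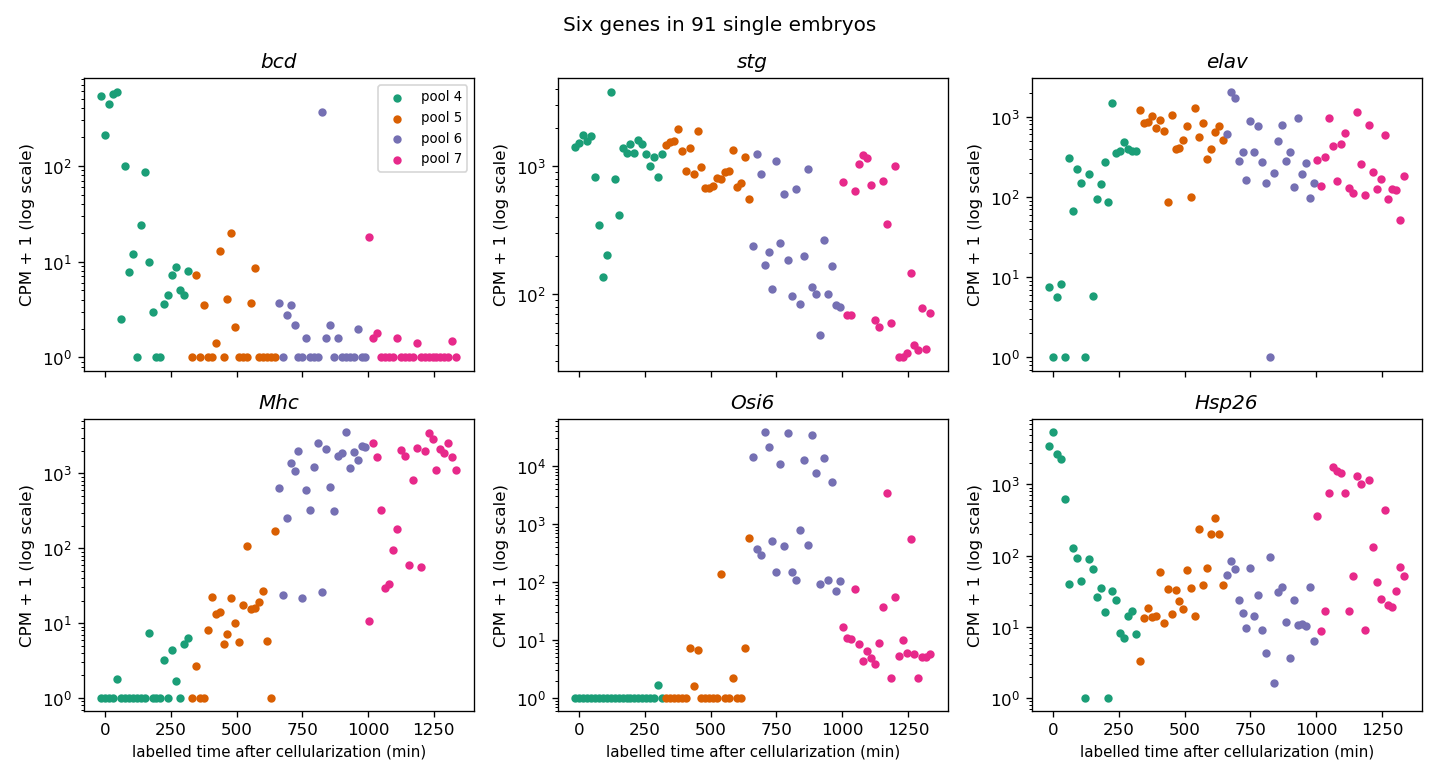
CPM + 1 on log axes against labelled time in minutes for bcd, stg, elav, Mhc, Osi6 and Hsp26 in 91 embryos, 1 point per embryo, coloured by library pool. Window means fell for bcd from 197 CPM in window 1 to 3.31 in window 2, were highest for Osi6 in window 5 at 9126 CPM, and for Mhc passed 400 CPM from window 4 on.

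The second question was how closely the transcriptome of an embryo followed its labelled time. The labelled time of the most similar other embryo correlated with an embryo's own labelled time over 91 embryos, with Pearson's r = 0.931 and Spearman's rho = 0.929. Both permutation p-values were 1e-05, the smallest the permutations can give, and 2e-05 and 3e-05 after adjustment over 6 relations. Without the 2 times farthest from the median the values were 0.930 and 0.928 (n = 89). Values were lower within single library pools, each of which spans a shorter stretch of time, which can by itself lower a correlation. Pearson's r was 0.772 in pool 4, 0.632 in pool 5 (p = 0.00167, adjusted p = 0.0025), 0.352 in pool 6 (p = 0.0961, adjusted p = 0.113) and 0.341 in pool 7 (p = 0.113, adjusted p = 0.113). Spearman's rho was 0.778, 0.686, 0.502 (adjusted p = 0.0195) and 0.435 (adjusted p = 0.0377) in the same pools. By adjusted p, in pools 6 and 7 the rank correlation thus lay under the threshold and the linear one did not. Pool 6 holds the embryo labelled 825 min, matched to 75 min, and its correlations were not taken without that embryo. Some embryos were each other's most similar, such as those at 765 and 855 min in pool 6, and each such pair entered with both members. The permutations treat embryos as independent, so all these p-values may be too small and the calls in pools 6 and 7 are not firm.

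The most similar embryo was a median of 75 min away, 30 min in pool 4, 67.5 min in pool 5 and 90 min in pools 6 and 7. It belonged to the embryo's own pool in 73 of 91 cases. In 21 embryos the distance was at most 30 min and in 9 it was over 195 min. The largest distance was 750 min. It was that of the embryo labelled 825 min, whose most similar embryo was labelled 75 min. That embryo held 362 CPM of bcd, the maternal determinant of the anterior, and 1892 CPM of smg, a regulator of maternal transcripts, with 25.4 CPM of Mhc and 0 CPM of elav, a gene of neurons. Its library was among the 6 shallow ones. By the second estimate of age, 14 embryos were estimated over 195 min younger than labelled and 6 over 195 min older.

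**Figure D3:**
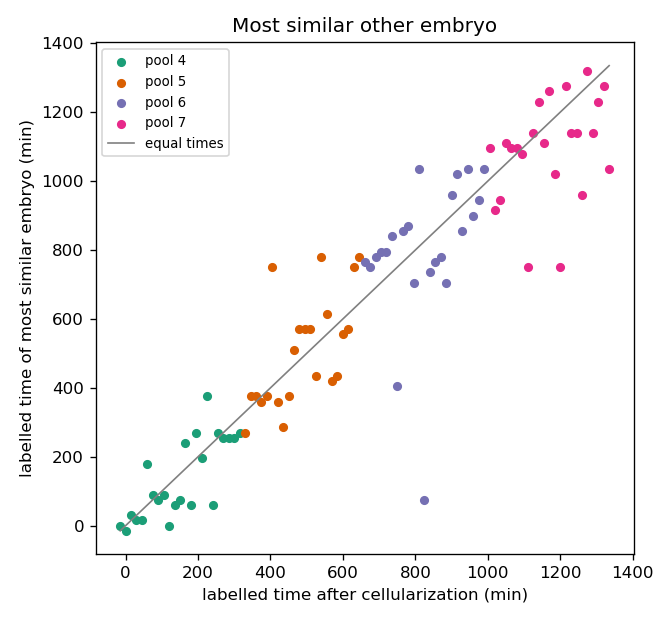
Labelled time of the most similar other embryo against an embryo's own labelled time, both in minutes, 1 point per embryo coloured by library pool, with the line of equal times. The point farthest from the line is the embryo labelled 825 min, matched to 75 min, and 9 embryos lie over 195 min from it.

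Window 1 spans cellularization and gastrulation, when egg transcripts give way to those of the embryo, and the trend in labelled time was tested in its 13 embryos, all of pool 4. Transcripts that fell outnumbered those that rose, with 1100 and 286 of 6483 tested genes (edgeR, adjusted p under 0.05). Values are log2 changes per 60 min ± SE. Among the transcripts that fell were Got2 (FBgn0001125), an aspartate aminotransferase, at -4.53 ± 0.50 (adjusted p = 5.99e-05), slif, an amino acid transporter gene, at -3.76 ± 0.42, and exu, which acts in placing bcd transcripts in the egg, at -3.68 ± 0.48. BigH1 (FBgn0038252), a linker histone of the early embryo, fell by 3.55 ± 0.45 per 60 min, from 980 ± 182 CPM in the first 3 embryos to 4.16 ± 7.20 CPM in the last 3. Rising genes included cv-2 (3.07 ± 0.83), which encodes a BMP-binding protein, Ama (2.74 ± 0.70), danr (2.93 ± 1.02) and the T-box gene Doc3 (2.67 ± 0.86).

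In the maternal list 14 of 19 members fell and none rose, and 16 fell when adjusted over the list alone. Examples were gnu (-3.04), BicC (-2.68), osk (-1.99), the organizer of germ plasm, and nanos (-1.96). Glycolysis genes fell in 7 of 12 cases (9 adjusted over the list alone), with Tpi at -3.12, Hex-A at -2.86 and Gapdh1 at -1.98. Heat shock genes fell in 5 of 7 cases (6 adjusted over the list alone), with Hsp27 at -2.55 and Hsp26 at -2.25. Ribosomal protein genes rose in 32 of 81 cases (57 adjusted over the list alone), RpL41 by 0.83 and RpS15 by 0.74. Their median of 0.54 was 0.27 with DESeq2 size factors and turned to -0.145 when libraries were scaled by spike-ins. The adjusted p of each of these 4 lists was 0.235 with an estimated correlation. Of the Hox genes 1 of 5 rose (4 adjusted over the list alone). It was Abd-B at 2.52, and without the embryo at 120 min its value was 2.08 and past the threshold no longer. Other members that rose were dpp (2.60), a BMP signal, byn (2.76), a hindgut gene, srp (2.30), a GATA factor, and roX1 (2.25 ± 0.68, from 12.0 to 489 CPM), a noncoding RNA of dosage compensation, while cad fell by 2.36 and hb fell by 0.84. For the trend within window 1 the median over all genes was -0.206 with the main scaling, -0.481 with DESeq2 size factors and -0.888 with spike-in scaling, and the share of calls that rose was 20.6%, 9.5% and 4.35%. Without the library at 120 min 664 genes rose and 1236 fell, a share of 34.9%.

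Between windows 1 and 2, from -15 to 165 and from 180 to 360 min, many maternal transcripts fell and genes of early organs rose. Of 5739 tested genes, 636 rose and 804 fell, 556 and 687 of them by at least 2-fold (edgeR, n = 13 per window). Drat (FBgn0033188) rose by 6.74 ± 0.73 on the log2 scale (SE; adjusted p = 1.4e-06), from 1.14 ± 1.95 to 139 ± 81.6 CPM, and all 13 later embryos lay above the earlier mean. The homeobox gene caup rose by 6.29 ± 0.83, the POU factor gene vvl by 6.11 ± 0.90 (5.38 to 433 CPM), Cph, a zinc finger gene, by 6.13 ± 0.85 and scrt, a zinc finger gene of neurons, by 5.90 ± 0.72. Tsp, the thrombospondin gene, rose by 5.66 and apolpp, the precursor of the main lipoprotein, by 5.55 ± 0.86. The fitted change of ct, another homeobox gene, was 5.41, and the library at 120 min, with 3662 counts, raised its CPM mean in window 1. Falling transcripts included BigH1 (-6.08 ± 1.04, from 351 to 4.01 CPM), Elba1, a gene of chromatin insulation (-6.33 ± 1.07), Jabba, a histone anchor of lipid droplets (-5.98 ± 0.89), Hsp26 (-5.88 ± 0.83, from 1145 to 14.1 CPM), Marf1 (-5.71), osk (FBgn0003015; -5.68 ± 0.83, from 279 to 3.74 CPM), Cyp6v1 (-5.62) and the nuclear receptor gene ftz-f1 (-5.54 ± 0.85).

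Maternal genes fell in 12 of 15 cases, with 13 falling and 1 rising when adjusted over the list alone (adjusted p = 0.26 with an estimated correlation). They included bcd (FBgn0000166; -5.53 ± 0.81), BicC (-5.01) and pgc (-4.76), a gene of germ cells. All 4 tested cellularization genes fell, also when adjusted over the list alone, with dunk at -4.18, term at -3.77, halo at -3.41 and Sry-alpha at -3.23 (adjusted p = 0.4 with an estimated correlation). Glycolysis genes fell in 7 of 11 cases and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.315 with an estimated correlation). Gapdh2 fell by 5.07 ± 0.79, from 509 to 9.38 CPM, Gapdh1 by 4.12 and Pglym78 by 3.94, and ERR, a regulator of glycolysis genes, rose by 1.29. Heat shock genes fell in 2 of 7 cases (2 adjusted over the list alone), Hsp26 and Hsp27 (-4.24 ± 0.77).

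Hox genes and genes of several organs rose in the same step. Hox genes rose in 4 of 5 cases (4 adjusted over the list alone; adjusted p = 0.26 with an estimated correlation), with abd-A at 3.42 ± 0.72 and Ubx at 3.23 ± 0.71. Neuroblast genes rose in 8 of 14 cases (8 adjusted over the list alone; adjusted p = 0.188 with an estimated correlation), led by the Notch targets E(spl)m7-HLH (3.50) and E(spl)m8-HLH (3.23). Trachea genes rose in 4 of 5 cases (4 adjusted over the list alone), with trh, a regulator of tracheal fate, at 4.75 and rib at 3.46 (114 to 1330 CPM). Hemocyte and fat body genes rose in 5 of 6 cases (5 adjusted over the list alone), with LanA, a laminin, at 4.61 and NimC4 at 3.56. Muscle genes rose in 4 of 7 cases (4 adjusted over the list alone), with Act87E at 4.36 and Mef2 at 1.96. For trachea, hemocyte and muscle lists the adjusted p was 0.167 with an estimated correlation. Neuronal genes rose in 3 of 7 cases, fne (3.16), elav (2.66) and futsch (from 2.22 to 10.5 CPM), and both glia genes tested, nrv2 (3.75) and gcm (2.43), rose, with the same counts adjusted over the list alone. In the gut and Malpighian tubule list 1 of 6 members rose, fkh (2.04; 2.04 and past the threshold no longer without the embryo at 120 min), and cad (-3.31) and Vha55 (-3.22) fell, with the same counts adjusted over the list alone (adjusted p = 0.924 with an estimated correlation), and from window 1 to window 2 its median was -0.41, and 1.3 with voom. The odorant-binding protein gene Obp99a rose by 4.80, from 239 to 3949 CPM. The sex determination list held 3 members of 8 that rose (4 adjusted over the list alone), roX2 (3.98), roX1 (from 301 ± 314 to 1122 ± 290 CPM) and tra (1.35). Of 81 ribosomal protein genes 4 rose (1 adjusted over the list alone), and of 23 cell cycle genes dpa rose (1.35) while CycB3 (-1.41) and mad2 (-1.12) fell. Among patterning genes, 0 of 14 gap and pair-rule, 0 of 6 segment polarity and 0 of 12 dorsoventral and gastrulation genes rose by edgeR, also when adjusted over the list alone, and from window 1 to window 2 limma voom called 5, 6 and 9 of them as risen. In edgeR 1 gap and pair-rule gene, eve (-2.49), and 1 dorsoventral gene fell.

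Within pool 4 alone, with 13 against 10 embryos, 490 genes rose and 540 fell, 941 of them also called with all embryos, and bcd changed by -5.20. Named calls lost there, with the same direction, included CycB3 (-1.11), mad2 (-0.945), roX1 (1.72), tra (1.21), eve (-2.36) and the dorsoventral gene fog (-1.24). Lost as well were the Hox gene Abd-B (2.45), the glia gene gcm (2.0), the gut gene fkh (2.13) and the neuroblast gene pros (2.29). The share of calls that rose was 44.2% with the main scaling, 31.3% with DESeq2 size factors and 29.5% with spike-in scaling, which called 799 genes, and the median over all genes was -0.0735, -0.295 and -0.482. Which direction held more genes was not settled. Without the embryo at 120 min 796 rose and 748 fell, voom called 1118 and 1091, all embryos in one fit gave 1486 and 848, and more genes rose than fell in 12 of the 26 fits that left out 1 embryo.

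From window 2 to window 3, with a start at 375 min, 121 genes rose and 79 fell of 5682 tested. A neuronal gene and heat shock genes were among those that rose. Rdl (FBgn0004244), a GABA receptor subunit, rose by 6.57 ± 1.00, from 3.22 ± 3.43 to 248 ± 392 CPM (adjusted p = 0.000746; 12 of 13 later embryos above the earlier mean), as 1 of 8 members of the neuronal list, also when adjusted over the list alone (adjusted p = 0.0798 with an estimated correlation). Inos, an enzyme of inositol synthesis, rose by 2.69 ± 0.54, Nlg4, a neuroligin of synapses, by 2.56 ± 0.59, the trehalose transporter gene Tret1-1 by 2.44 and Lpin, a phosphatidate phosphatase, by 2.00 ± 0.39. Heat shock genes rose in 4 of 8 cases and in 7 when adjusted over the list alone (adjusted p = 0.0798 with an estimated correlation), with Hsp68 at 3.15 ± 0.66, Hsp70Aa at 2.11, Hsp70Ab at 1.97 and Hsp83 at 0.89. In window 3 the libraries at 435, 465, 480, 510, 525 and 555 min held over 6% spike-ins, as did those at 210 and 315 min in window 2. Without these edgeR called 0 genes (1180 at an unadjusted p under 0.05), and from window 2 to window 3 Hsp68 was at 1.66, the heat shock median went from 1.42 to 0.465, and Rdl was at 2.49. CycB3 (FBgn0015625), a mitotic cyclin, fell from 1408 ± 1361 to 488 ± 224 CPM (adjusted p = 0.0288), Doc3 fell by 1.73 ± 0.33 on the log2 scale, tex fell by 1.96 and Delta, the Notch ligand, fell by 1.11 ± 0.21.

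Cell cycle genes fell in 2 of 23 cases (2 adjusted over the list alone), CycB3 and fzy (-0.95), a regulator of mitotic exit. Gap and pair-rule genes fell in 2 of 13 cases (4 adjusted over the list alone), slp1 (-1.38) and run (from 96.0 to 45.9 CPM). Oxidative phosphorylation genes fell in 5 of 57 cases (6 adjusted over the list alone; adjusted p = 0.408 with an estimated correlation), ND-AGGG by 1.51 and ND-15 by 1.14. The list medians of these 3 were negative under every scaling tried. Msp300, a muscle gene, rose by 1.40, Eno, an enzyme of glycolysis, by 1.66 and tud, a germ plasm gene, by 1.05. Of the ribosomal protein genes RpS5a (0.59) and RpL21 (0.55) rose and RpL34b (-0.72) and RpL34a (-0.66) fell. In pool 5, where 3 embryos of window 2 met 13 of window 3, edgeR called 0 genes, with 416 at an unadjusted p under 0.05, and Rdl changed by 5.45 (adjusted p = 0.861), the heat shock median was 1.37 and RpL34b was at 0.106. Spike-in scaling called 7 genes, of which 85.7% rose against 60.5% in the main test, and leaving out the embryo at 180 min gave 111 calls and that at 225 min 349.

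From window 3 to window 4, with a start at 570 min, genes of muscle and glycolysis were among the 14 that rose, against 1 that fell of 5546 tested. Each named call had an adjusted p of 0.045. Mhc rose by 4.93 ± 1.01, from 18.1 ± 26.9 to 432 ± 652 CPM, with 10 of 13 later embryos above the earlier mean. Elovl7, by name a fatty acid elongase gene, rose by 5.14 ± 1.11, Cngl by 4.44 ± 1.00, qless, an enzyme of ubiquinone synthesis, by 3.82 ± 0.74, its partner gene Pdss2 by 2.40 ± 0.50 and the cuticle gene TwdlY by 3.76 ± 0.85. Gapdh2 rose by 3.23 ± 0.72 and Eno by 1.48 ± 0.34, and RpL34b by 0.92. The gene that fell was E(spl)malpha-BFM (FBgn0002732), a Notch target, at -1.74 ± 0.37, lower in 13 of 13 later embryos.

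From window 3 to window 4 muscle genes rose in 1 of 17 cases, and in 11 when adjusted over the list alone, with a median of 1.95 (adjusted p = 0.385 with an estimated correlation). Of 12 neuronal genes none was called over all genes and 7 rose when adjusted over the list alone, with a median of 1.58 (adjusted p = 0.358 with an estimated correlation). Glycolysis genes rose in 2 of 10 cases (5 adjusted over the list alone). The 57 oxidative phosphorylation genes had a median of 0.74 and the 22 cell cycle genes one of -0.66, with no call over all genes in either list and 1 fall in the second adjusted over the list alone. In pool 5, with 13 against 6 embryos, Mhc was at 1.23 (adjusted p = 1.0), the muscle median at -0.0119 and the neuronal median at 0.127. There edgeR called 0 genes, with 133 of 6378 at an unadjusted p under 0.05, fewer than chance gives. The count rested on single libraries: leaving out 23 of the 26 embryos in turn moved it by over 1.5 times, to 49 calls without the embryo at 540 min and to 0 by edgeR for 17 embryos (605 to 809 at an unadjusted p under 0.05), those at 375, 390, 420 to 510, 555 and 645 to 735 min.

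From window 4 to window 5, with a start at 765 min, 6 genes fell and none rose of 6275 tested by edgeR, against 1023 at an unadjusted p under 0.05. Tom (FBgn0026320), a Bearded family member of Notch signalling, fell by 3.72 ± 0.77, from 743 ± 970 to 57.1 ± 74.2 CPM. The fall of link was 3.30 ± 0.68. The gene dpa (FBgn0015929), a subunit of the replicative helicase, fell by 2.53 ± 0.47 (adjusted p = 0.0364), from 105 ± 78.2 to 17.9 ± 14.6 CPM, and all 13 later embryos lay below the earlier mean for each of these genes. The remaining calls were CG4440 (-6.21 ± 1.17), CG13427 (-5.03 ± 1.00) and FBgn0024332 (-3.10 ± 0.64), named after their values were seen. Cell cycle genes fell in 1 of 21 cases and in 10 when adjusted over the list alone, with a median of -1.34 (adjusted p = 0.203 with an estimated correlation). Neuroblast genes had a median of -1.46, with 0 of 12 called over all genes and 7 falling when adjusted over the list alone, and heat shock genes fell in 3 of 5 cases adjusted over the list alone and in none over all genes (for both, adjusted p = 0.203 with an estimated correlation). Neuronal and glycolysis medians were 1.23 and 1.26, with no member called over all genes and 2 glycolysis genes rising when adjusted over the list alone.

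In pool 6, with 7 against 13 embryos, Tom was at -1.51 and dpa at -1.66, the cell cycle median at -0.473 and the neuroblast median at -1.06. There edgeR called 0 genes, with 239 of 7198 at an unadjusted p under 0.05, fewer than chance gives. The 6 calls rested on single libraries. Leaving out 1 embryo ended every call for 16 of the 26, those at 570 to 630, 750, 765, 795, 810, 840, 855 and 885 to 945 min (0 by edgeR, 825 to 1016 at an unadjusted p under 0.05), and so did leaving out libraries above 6%, 8% or 10% spike-ins (920, 1113 and 944 unadjusted). Without the shallow library at 825 min 303 genes were called and without the embryo at 735 min 273, while DESeq2 called 293 genes and voom 253, of which 200 rose and 53 fell.

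From window 5 to window 6, with a start at 960 min, heat shock genes rose in the test of all embryos, with high levels in libraries of high spike-in share. In window 6 the libraries at 1005, 1050, 1065, 1080, 1095 and 1110 min, with 6.8% to 10.1% spike-ins, held 360 to 1728 CPM of Hsp26, and the other 7, with 3.2% to 5.28%, held 5.4 to 50.5 CPM. Without libraries above 6% or 8% spike-ins edgeR called 0 genes (1717 and 1104 at an unadjusted p under 0.05), and from window 5 to window 6 the heat shock median was 0.386 and 1.24. Hsp70Ab rose by 5.66 ± 1.21, Hsp70Aa by 5.53 ± 1.20 and Hsp26 (FBgn0001225) by 5.07 ± 0.96, the last from 20.6 ± 24.8 to 515 ± 657 CPM (adjusted p = 0.0195; 8 of 13 later embryos above the earlier mean). Together with the cochaperone gene DnaJ-1 (2.04 ± 0.47) they were 4 of 7 members of the list that rose, and all 7 rose when adjusted over the list alone, with a median of 3.11 (adjusted p = 0.493 with an estimated correlation). In all 30 genes rose and 4 fell of 6198 tested. Other rising genes were sca (3.36 ± 0.70), a secreted protein of neurogenesis, Buffy (2.75 ± 0.57), a Bcl-2 family gene, Pino (2.57 ± 0.59), Mipp1 (2.26 ± 0.52), a phosphatase of inositol phosphates, and crb (2.36 ± 0.52), a gene of epithelial polarity. The falling genes were CG12522 (-5.28 ± 0.95), CG14756 (-4.77 ± 0.87), CG5850 (-2.21 ± 0.43) and CG2147 (-1.96 ± 0.44), named after their values were seen.

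Of 82 ribosomal protein genes tested from window 5 to window 6, RpS29 (0.57) and RpL37A (0.57) rose, and 66 rose when adjusted over the list alone, with a median of 0.39 that turned to -0.251 with spike-in scaling (adjusted p = 0.914 with an estimated correlation). The cell cycle median was 0.96, with 0 of 20 members called over all genes and 2 rising when adjusted over the list alone, and it was -0.0204 with spike-in scaling, -1.65 within pool 6, and -1.19 and -0.224 without libraries above 6% and 8% spike-ins. In pool 6, where 13 embryos met 3, Hsp26 was at 0.17, the heat shock median at 0.0646 and crb at -0.0942. The other rising genes named above were smaller there too, sca at 0.0765, Pino at 0.245, Mipp1 at 0.701 and Buffy at 1.32. There edgeR called 0 genes, with 215 of 8188 at an unadjusted p under 0.05, fewer than chance gives. Spike-in scaling called 315 genes, of which 2.54% rose against 88.2% in the main test and 75% with DESeq2 size factors, and moved the median of all genes from -0.0192 to -0.541. Hsp26 stood at 1728 CPM in the embryo at 1065 min, 1518 at 1080 min and 1433 at 1095 min, and the estimated times of these 3 embryos were 570, 555 and 600 min. The embryos at 1005 and 1050 min had estimated times of 540 and 675 min. All of these libraries held over 8% spike-ins, so the rises of this step may reflect embryos whose profiles lie far from their label. The count was 5 without the embryo at 780 min and 192 without that at 915 min, and 23 of the 26 embryos moved it by over 1.5 times.

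From window 6 to window 7, with a start at 1155 min, edgeR called 0 of 6151 genes, with a smallest adjusted p of 0.297, and 781 genes had an unadjusted p under 0.05 where 308 would by chance. DESeq2 called 61 genes, voom 0 (746 at an unadjusted p under 0.05) and the fit of all 91 embryos 20. Cell cycle genes fell in 9 of 17 cases when adjusted over the list alone and in none over all genes. Their median was -1.70, and -1.86 within pool 7 (adjusted p = 0.423 with an estimated correlation), and from window 6 to window 7 it was -0.133 without libraries above 6% spike-ins and -1.03 without those above 8%. In window 6 the libraries at 1005, 1050, 1065, 1080, 1095 and 1110 min, all above 6%, held 637 to 1226 CPM of stg, a phosphatase of mitotic entry, and the others 54.1 to 164 CPM. In window 7 the libraries at 1155, 1170 and 1200 min, all above 8%, held 766, 354 and 995 CPM. Gap and pair-rule genes had 3 falling and 1 rising when adjusted over the list alone and none over all genes. Medians of other lists were 0.63 for neuronal, 0.42 for muscle and 0.91 for glycolysis genes, with none called over all genes, and 0.165, 0.0907 and 0.348 without libraries above 6%.

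Library pool follows age, and the shared pool held few embryos of 1 of the windows in most steps, those nearest in age to the other window, so a call lost there does not by itself tell a difference between pools from a change with age. Some folds were about as large in the shared pool, with wider errors. From window 2 to window 3 Rdl was at 5.45 ± 1.95 against 6.57 ± 1.00 with all embryos, Lpin at 1.74 ± 0.65 against 2.00 ± 0.39 and Eno at 2.18 ± 0.86 against 1.66 ± 0.43. Most named folds of that step were smaller in the shared pool, though. Inos was at 1.27 ± 0.615 against 2.69 ± 0.535 and tex at -0.344 ± 0.799 against -1.96 ± 0.425. In later steps, too, named folds were smaller in the shared pool, most of them by more than their SE. An exception was Eno from window 3 to window 4, at 1.14 ± 0.43 against 1.48 ± 0.34. Mhc from window 3 to window 4 was at 1.23 ± 0.87 against 4.93 ± 1.01. Hsp26 from window 5 to window 6 was at 0.17 ± 0.87 against 5.07 ± 0.96. The embryos of both fits overlap and the differences between them were not tested. The 64 list calls made with a preset correlation over the 7 comparisons came to 0 with an estimated correlation. Spike-in scaling moved the median of all genes from 0.0372 to -0.182 from window 3 to window 4 and from 0.00967 to -0.107 from window 6 to window 7, and DESeq2 size factors moved it from 0.166 to 0.306 from window 4 to window 5.

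**Figure D4:**
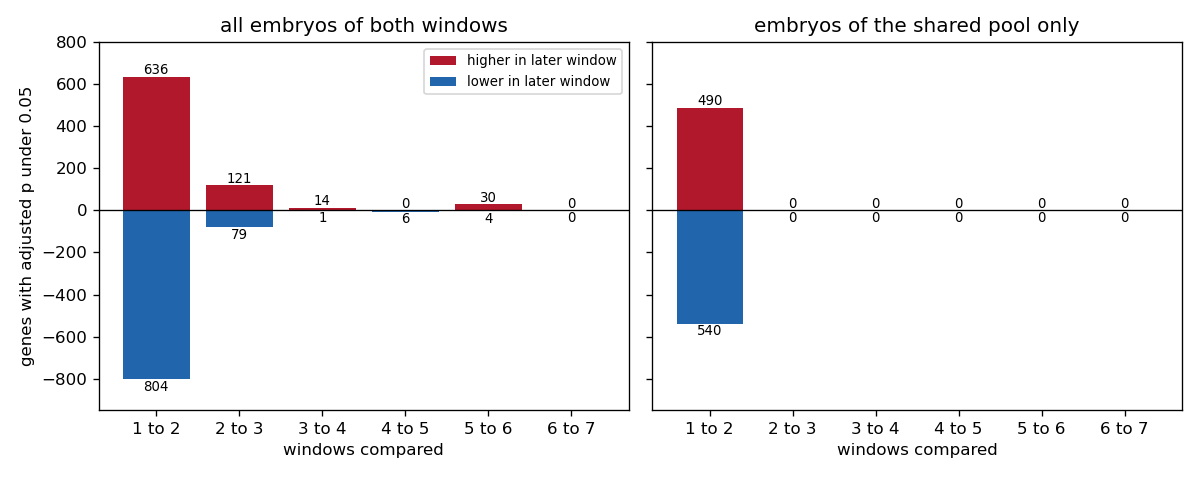
Number of genes that rose and fell between adjacent windows at an adjusted p under 0.05, with all 26 embryos of each pair (left) and with the embryos of the shared library pool (right). In the shared pool 490 genes rose and 540 fell from window 1 to window 2, and no genes were called in the other 5 steps.

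The level of roX1, a noncoding RNA of dosage compensation, ran over a wider fold range in late embryos than in those labelled 180 to 645 min. The 32 embryos labelled 180 to 645 min all held over 400 CPM of roX1 (FBgn0019661), with a median of 1029 and a range from 412 to 1533 CPM. The 46 embryos labelled 660 min and later had a median of 110 and a range from 9.2 to 972 CPM, with 18 above 400 and 23 under 100 CPM. Both ends came from shallow libraries, those at 825 and 1065 min, with estimated times of 90 and 570 min. The embryos at 975 and 720 min, not shallow, held 9.9 and 942 CPM. Among the 18 above 400 CPM were those at 1005, 1065, 1080 and 1095 min, with estimated times from 540 to 600 min. For roX2 (FBgn0019660) the medians were 79.6 (0 to 180) and 34.4 (0 to 179) CPM, and for Sxl, the switch gene of sex determination, 231 (97.9 to 1171) and 298 (18.5 to 806) CPM. At 915 min roX1, roX2 and Sxl stood at 839, 157 and 130 CPM, and at 945 min at 17.9, 2.7 and 322 CPM. Not all late embryos followed either pattern: at 1005 min the values were 609, 25.5 and 452 CPM. The labels used here do not give the sex of the embryos, so a late median may mix both sexes. Whether sex accounts for the spread was not tested. The border at 660 min, which is also the border between the lanes, and the limits of 400 and 100 CPM were chosen after the values were seen, and no test was run on them.

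**Figure D5:**
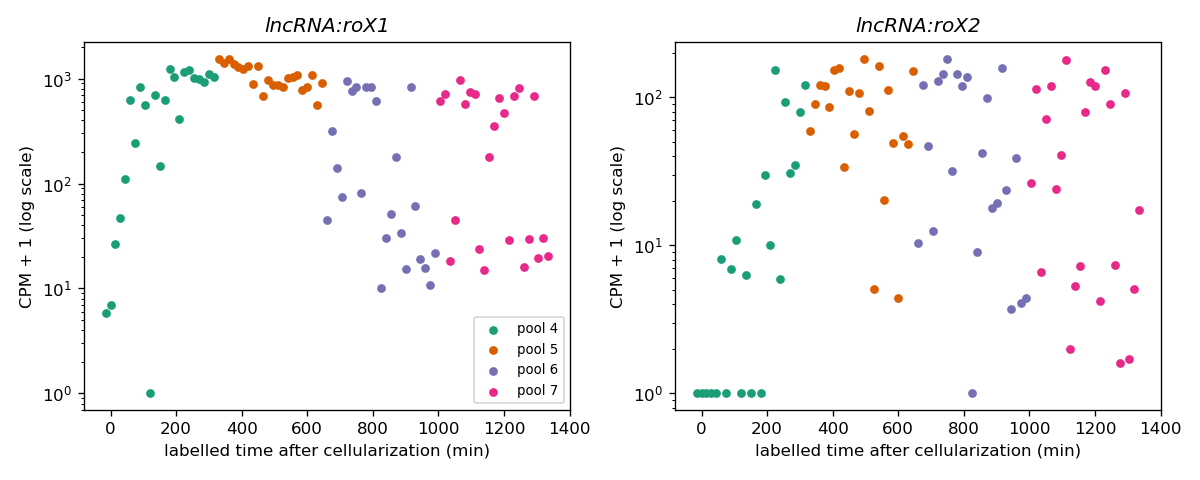
CPM + 1 on log axes against labelled time in minutes for roX1 and roX2, 1 point per embryo coloured by library pool. From 180 to 645 min roX1 stays between 412 and 1533 CPM, and from 660 min on it runs from 9.2 to 972 CPM.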

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

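Both tests of label swaps, the signed-rank test and the 4 tests on the number of detected genes were chosen after the results they concern had been seen; the signed-rank test was added once the planned count on the same libraries had missed its threshold.

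Embryos with late labels whose profiles matched earlier times were the first pattern. The estimated time was 90 min for the embryo labelled 825 min, 540 for 1005, 570 for 1065, 555 for 1080, 600 for 1095 and 630 for 1155 min. Low depth as the cause is argued against, since thinning to 400000 gene counts moved 0% of 61 libraries by over 195 min, although these libraries had started near their label. Swaps of labels within the series are argued against for 8 of 11 such libraries labelled 660 min and later, those at 825, 1005, 1050, 1065, 1080, 1095, 1155 and 1200 min, which had no partner over 195 min too old with label and estimate each within 195 min of theirs, and stay open for 1170, 1260 and 1335 min, since the 6 embryos too old and 14 too young over the whole series do not decide (exact two-sided binomial p = 0.115), as do single wrong labels, which need no partner. Loss of late transcripts in libraries of low RNA yield, which would not raise early transcripts per spike-in, may be a candidate cause too. Cell cycle counts per spike-in count lay above the pool median in 8 of 10 such libraries of pool 7. By the planned test that is too few to exclude it (exact one-sided binomial p = 0.0547). Their values ran from 0.0044, below the pool median of 0.0071, to 0.0623. Taken by size, the values argue against such a loss for these libraries as a set (exact one-sided signed-rank p = 0.00977). The support is weak, because the pool median includes these libraries. They were also picked by their early profiles, which may favour high cell cycle counts, so this p-value is not that of an independent test. Slow or arrested development of single embryos was not tested.

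The larger number of genes detected from 660 min on was the second pattern. A difference in depth as the whole cause is argued against, since at equal depth 7390 ± 826 genes were detected on lane 4 and 6210 ± 758 on lane 3, with a permutation p of 1e-05, the smallest possible. A library or lane batch may contribute: spike-in species, which have no age, numbered 77.6 ± 5.22 on lane 4 (n = 46) and 72.0 ± 6.77 on lane 3 (n = 45) at 30000 spike-in counts, with a permutation p of 4e-05. Both permutation tests treat embryos as independent although whole pools lay on a lane, so both p-values may be far too small. A steady rise with age as the sole cause is argued against, since the slope within lanes was -42.9 genes per 60 min (95% interval -93.0 to 7.24) and the difference between lanes needs 105. Beside differences between pools, in which spike-in species fell as well (73.5 to 70.5 from pool 4 to pool 5 and 79.1 to 76.2 from pool 6 to pool 7), a rise stays open, as the slope within pools was 22.6 (-76.2 to 121), and a change near the border of the lanes cannot be told apart from lane or pool.

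The library at 120 min was the third, set apart by a signal outside the gene measurement: spike-ins took 96.0% of its gene and spike-in counts. Its 3662 gene counts held 6 counts of the maternal list, with an exact Poisson interval of 2.2 to 13.1 that covers counting error only. Reads of other libraries of the pool would give 10.7 such counts and an embryo of the labelled age, by its neighbours at 105 and 135 min, 3.87. Both lie in the interval, so by these counts either could be the source, and the counts are too few to separate them. The library also held 1.07 counts outside annotated genes per gene count. At 105 and 135 min that ratio was 0.285 and 0.256, and the highest of the other libraries, at 210 min, had 0.474. By these values neither source alone would give the ratio at 120 min, and its cause was not tested.

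Of all counts in the table, 16.6% lay outside annotated genes, data that the comparisons do not use.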

How the results depend on the processing

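Scaling by spike-ins, fits in a single pool, leaving out the embryo at 120 min, each embryo in turn or libraries above 6%, 8% or 10% spike-ins were chosen after the data had been seen; the percentages were set once these libraries' profiles were known. Pool as a covariate was not run for the trend in window 1, whose embryos are all of pool 4. No paired analysis was possible because each embryo was sampled once and nothing links embryos across windows. Counts below are genes called and, unless said otherwise, the cause was not tested.

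The median distance to the most similar embryo was 75 min in all 4 alternatives run. Counts from window 1 to window 2 changed from 1440 to 3808 without a filter on low counts, which tests more genes, 2180 with DESeq2, 2209 with voom, 2334 with all embryos in one fit and 799 with spike-in scaling. From window 2 to window 3 the count of 200 became 1572 without a filter, 457 with DESeq2, 347 with voom, 358 in one fit, 7 with spike-in scaling, and 0 by edgeR with pool as a covariate (242 at an unadjusted p under 0.05), in one pool (416) and without libraries above 6% spike-ins (1180). From window 3 to window 4 the count of 15 became 1772 without a filter, 9 after thinning, 193 with DESeq2, 1004 in one fit, 0 by edgeR with pool as a covariate (177 unadjusted), in one pool (133) and with spike-in scaling (795), and 305 and 26 without libraries above 8% and 10%, with 13 at 6%; voom called 11.

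From window 4 to window 5 the count of 6 became 137 without a filter, 303 without shallow libraries, 314 after thinning, 293 with DESeq2, 253 with voom, 270 in one fit, and 0 by edgeR with pool as a covariate (150 unadjusted), in one pool (239), with spike-in scaling (491) and without libraries above 6%, 8% or 10% (920, 1113 and 944). From window 5 to window 6 the count of 34 became 20 with DESeq2 size factors, 59 with a stricter filter, 16 without shallow libraries, 65 after thinning, 381 with DESeq2, 1 with voom, 168 in one fit, 315 with spike-in scaling, 19 without libraries above 10%, and 0 by edgeR with pool as a covariate (90 unadjusted), in one pool (215) and without libraries above 6% or 8% (1717 and 1104). From window 6 to window 7 the count of 0 became 1 without a filter, 61 with DESeq2 and 20 in one fit.

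The trend count of 1386 became 2157 with DESeq2 size factors, 2101 without a filter, 896 with a stricter filter, which tests fewer genes, 2775 with DESeq2, 515 for the first 6 against the last 6 embryos, 2093 with spike-in scaling and 2158 without libraries above 6%. The spline count of 7155 became 11429 without a filter, 3146 with pool as a covariate and, in fewer embryos, 3412, 0, 5 and 2 in pools 4 to 7, with 549 at an unadjusted p under 0.05 in pool 5. The 64 list calls became 0 with an estimated correlation. The 55 other alternatives were within 1.5 times or equal. They include the 4 of the distance to the most similar embryo and those with 0 against 0 calls from window 6 to window 7. Some gave equal counts: the trend had 1900 calls without shallow libraries, without the embryo at 120 min and without libraries above 8% or 10% spike-ins.

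Leaving out 1 embryo at a time gave 1225 to 1645 calls from window 1 to window 2, 111 to 349 from window 2 to window 3, and 0 to 49, 0 to 303, 5 to 192 and 0 to 0 in the later steps. From window 2 to window 3 it moved the count by over 1.5 times for the embryos at 180 (111), 195 (119), 225 (349), 240 (116), 255 (124), 270 (119) and 555 min (115); in the next 3 steps it did so for 23, 24 and 23 of 26 embryos.

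The 182 values of 154 named genes kept direction and side of the threshold in 1949 cases, lost the call in 429 and reversed in 7. RpS28b (trend) went from 0.68 to -0.0171, RpS29 from 0.57 to -0.108 and RpL37A from 0.57 to -0.0929 (window 5 to window 6) with spike-in scaling. RpL34b (window 2 to window 3) went from -0.72 to 0.106 in one pool and 0.137 with pool as a covariate, and crb (window 5 to window 6) from 2.36 to -0.0942 and -0.134. Most lost calls came with spike-in scaling (76), with 1 pool (70 of 131), pool as a covariate (68 of 131) and without libraries above 6% spike-ins (60). Thinning left 3980 of 5739 genes tested from window 1 to window 2. In simulated counts 18%, 23% and 13% of genes changed by a log2 of 1 were recovered in steps from windows 1, 3 and 6, at the real depths and spread between embryos, whose shares were not separated.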

Other observations

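No test was run on the values in the first 2 paragraphs, and their genes and embryos were chosen after the values were seen. The splits of the samples in the last paragraph were fixed before. Osi6 (FBgn0027527), a gene of the Osiris family expressed in cuticle-forming epithelia, had window means of 5882 ± 11912 CPM in window 4 and 9126 ± 12900 CPM in window 5, against 11.6 ± 38.1 in window 3 and 425 ± 1439 in window 6. The highest value was 38371 CPM at 705 min. In pool 6 the lowest was 67.7 CPM, at 975 min. The digestive proteases Jon25Bi and alphaTry stood out in a pair of late embryos, with 840 and 1233 CPM at 1290 min and 1085 and 1332 CPM at 1305 min.

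The nuclear receptor genes Hr3 and ftz-f1, which act in succession in responses to ecdysone, differed in level within single embryos. At 930 min Hr3 stood at 1041 CPM and ftz-f1 at 22.5 CPM, and at 840 min ftz-f1 stood at 645 CPM and Hr3 at 70.6 CPM. The embryo labelled 225 min held 765 CPM of Hr3 and 1482 CPM of elav, and its estimated time was 600 min. The embryo labelled 1005 min held 9.7 CPM of Mhc and 360 CPM of Hsp26. Other embryos labelled 1155, 1170 and 1200 min held 1323, 1024 and 1158 CPM of Hsp26, with estimated times of 630, 720 and 645 min and spike-in shares of 8.55%, 13.5% and 8.39%.

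Whether the counts of changed genes could come from any grouping of the embryos was tested with 100 splits of each pair of windows, the real split included. The splits ignore library pool, so they do not separate window from pool. They also mix neighbouring times, which the real split keeps together, so any drift over the series favours the real split. From window 1 to window 2 the real split, with 1440 genes, was the 1 split with as many, and the highest other gave 90. A random grouping of these embryos is argued against there. From window 2 to window 3 the real split was again the 1 with as many (200 genes, highest other 136). That step gave 111 genes without the embryo at 180 min. From window 3 to window 4 it was so too (15 genes, highest other 6). Leaving out 1 embryo there gave 0 calls by edgeR for 17 of 26 (605 to 809 at an unadjusted p under 0.05). These 2 steps are not settled by the splits. From window 4 to window 5 as many as the real 6 genes came from 3 splits and the highest other gave 61, and from window 5 to window 6 as many as the real 34 came from 3 splits, with 172 as the highest other. In these 2 steps 3 of 100 is a share under 0.05, but some other splits called several times the real number. What sets those splits apart was not tested. In the shared pool edgeR called 0 genes in the steps from window 2 to window 6. Unadjusted p-values under 0.05 numbered 416 of 7349, 133 of 6378, 239 of 7198 and 215 of 8188 tested genes. All but the first lie below the share of 0.05 that chance gives. From window 6 to window 7, with 0 genes called by edgeR, 781 at an unadjusted p under 0.05, 61 by DESeq2 and 0 by voom, all 100 splits reach a count of 0 by construction and the highest other gave 3, so this test says nothing about chance.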
